A study of Mus musculus with 2 samples.

How the data were processed

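The series holds 2 expression arrays of mouse cerebral cortex, 1 for wild-type mice and 1 for mice titled as Gnmt knockouts, each hybridised with RNA pooled from 3 males aged 4 weeks. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 5 micrograms of it by the Affymetrix procedure. The deposited values are linear intensities, 1 signal per probe set and array; GCOS, the Affymetrix operating software, is named in the submitters' processing notes. Its version, signal algorithm and detection calls are not given in the sources used here. In the deposited table the mean of each array after trimming 2% of the values at either end was 500.0, so the arrays had been scaled to a common mean before deposit. Signals ran from 0.2 to 46616 units. A common mean fixes the average but not the spread, so the higher median of the knockout-labelled array (124.9 against 92.0 units) was left in the data and treated by the alternatives.

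Samples were grouped by their titles, since the genotype entry of the knockout-titled sample reads wild-type. No detection calls were used, and a floor took their place: the 40th percentile of all non-control signals of both arrays, 64.2 units. A probe set counted as measured when it reached the floor on both arrays, as 23928 did. The log2 ratio of the knockout-labelled over the wild-type array was centred by subtracting its median over these probe sets, 0.01. After this step the median over genes was -0.06.

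Gene names came from the platform annotation table given with the data. Of 45037 non-control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none. Of those with 1 symbol, 34741 matched the RefSeq gene table of assembly GRCm38.p6 by gene identifier and took its current symbol. That table was used only for names, gene lengths, classes and which genes neighbour each other, because the build behind the annotation is not given in the sources used here. A gene was represented by the probe set with the highest mean log2 signal, which gave 18193 named genes and 12244 measured on both arrays. Probe sets naming several genes or none were left out of gene values. Where a gene was below the floor on 1 array, the ratio of the other array's signal to the floor, centred in the same way, is given as a lower bound.

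Probe set error was taken as the SD of the difference between the log2 ratios of the 2 brightest probe sets of a gene, divided by the square root of 2. It covers differences between probe sets on the same RNA and not the spread between mice or pools. With 1 array per group no p-value, standard error of a group mean or count of significant genes was calculated, and the number of arrays limits the precision of every value.

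Gene lists were fixed before the data were examined. For each list with at least 4 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn with replacement within 10 bins of mean signal. A list is said to stand apart when its median fell in the lowest or highest 2.5% of these. Members are counted as higher or lower from 1.5-fold. The percentile describes these 2 arrays and is no test of genotype.

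The genes named follow a rule also fixed before the data were examined: Gnmt, the 12 highest and 12 lowest ratios, the 10 highest and 10 lowest among genes with every measured probe set at least 1.5-fold apart in 1 direction, up to 3 members at either end of each list, and the 4 genes each way with the largest signal over the floor where the other array was below it. The sex-linked genes were a list of the design. The other pituitary, hypothalamic, actin and nuclear noncoding genes named in the closing section were chosen after their pattern had been seen.

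The calculations were tested on simulated data made from the wild-type against knockout comparison, with 12596 genes in the simulated table. Shifts of log2 1 and -1 came back as 0.99 and -0.98, and shifts of 2 and -2 as 1.82 and -2.03. A simulated error SD of 0.50 came back as 0.50, and 4.38% of unshifted genes passed 2-fold. The simulated SD lay below the probe set error SD of 0.58 in these arrays. The 4.38% therefore understates how many genes that error would put past 2-fold. Of 100 lists of 20 genes shifted by 0.5, 97 stood apart, as did 5.0% of 200 unshifted lists. Members of the simulated lists were drawn at random with independent errors, whereas genes of a complex or cell type may vary together.

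Alternatives covered the floor (25th or 60th percentile, or none, with signals under 1 set to 1), the scaling (no centring, quantile normalization, or loess of ratio on mean signal with a fraction of 0.3), the probe set standing for a gene (median of all), suffixed probe sets left out, and random lists not matched on signal. The second brightest probe set was added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.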

Results

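Transcript levels were measured in the cerebral cortex of mice on 2 Affymetrix expression arrays. One array received RNA mixed in equal parts from 3 wild-type males aged 4 weeks, and the other received the same kind of mixture from 3 males of that age titled as Gnmt knockouts. Both pools came from a mixed 129/B6 background. Gnmt encodes glycine N-methyltransferase, an enzyme that passes a methyl group from S-adenosylmethionine (SAM) to glycine and makes sarcosine. The arrays carried 45101 probe sets each, of which 64 were controls. The median signal was 92.0 units in the wild-type pool and 124.9 units in the knockout-labelled pool, and 57.0% and 63.1% of the other probe sets reached the floor of 64.2 units. With 1 array per genotype there was no replicate, so no difference between the pools could be tested and every ratio describes these 2 pools alone.

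The targeted gene could not be used to check which pool was which. The single Gnmt probe set gave 10 units in the wild-type pool and 21.5 units in the pool titled knockout, both below the floor. The title of the second sample calls it a knockout while its genotype entry says wild-type, and the samples were grouped by title. The deleted part of Gnmt is not given in the sources used here, so a probe set outside it would have checked nothing.

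The growth hormone gene gave the lowest ratio between the pools, and an RNA of the inactive X chromosome gave the highest lower bound. Gh, which encodes growth hormone, had a signal of 23223 units in the wild-type pool and 200 units in the knockout-labelled pool, a 117-fold difference by its brightest probe set, with a log2 ratio of knockout-labelled over wild-type of -6.87. All 4 Gh probe sets lay between -6.93 and -6.25. Pomc, the precursor gene of corticotropin and melanocortins, was 8.0-fold higher in the wild-type pool, the ninth lowest ratio. Prl, encoding prolactin, and Cga, encoding the shared alpha chain of the glycoprotein hormones, were above the floor in the wild-type pool alone, at 2351 and 2362 units. Their signals were at least 36.9-fold and 37.1-fold higher there. In the other direction, Xist, the noncoding RNA that coats the inactive X chromosome of female cells, gave 49.6 units in the wild-type pool and 2560.3 units in the knockout-labelled pool, at least 39.6-fold higher. A second Xist probe set was at least 14.8-fold higher. The Y-linked genes Eif2s3y, Uty and Kdm5d were above the floor in both pools, with log2 ratios of 0.16, -0.22 and -0.85, and both pools are labelled male.

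Outside the hormones, Rpl22l1 and Serpina3n had the lowest ratios of knockout-labelled over wild-type signal. Rpl22l1, a paralog of a ribosomal protein gene, had 8043 and 651.4 units and was 12.4-fold lower. Serpina3n, a serine protease inhibitor made by reactive astrocytes, was 10.9-fold lower. Zfp931, Cfap36, Pttg1, Hmgn5, Pfdn4 (a prefoldin subunit), Dnajc2 (a ribosome-associated chaperone partner), Nsa2 (a ribosome biogenesis factor) and Zfp942 had log2 ratios between -3.25 and -2.73. Zfp386 and Ikbip were above the floor in the wild-type pool alone, at least 9.34-fold and 7.28-fold higher.

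The genes highest in the knockout-labelled pool had mostly low or moderate signals in the wild-type pool. Zdhhc21, encoding a protein palmitoyltransferase, was 18.3-fold higher, with 131.8 and 2436 units, and its other probe set had a log2 ratio of 0.72. Crim1, encoding a transmembrane protein that binds bone morphogenetic proteins, was 15-fold higher, and its other probe set had 1.75. Sdc4, a cell-surface proteoglycan gene, was 6.83-fold higher, Kcnma1, the gene of the BK potassium channel, 5.81-fold and Msi2, an RNA-binding protein gene, 5.70-fold. C030023E24Rik, Paqr9 and Agap1 had log2 ratios of 2.71, 2.51 and 2.45. Over all probe sets the medians of Msi2 and Agap1 were only 0.84 and 0.85. Several of the 12 highest genes had other probe sets with the opposite sign, such as -0.16 for Kcnma1 and -0.76 for Paqr9. Rbfox2, a splicing factor gene, had a ratio of 3.44 by its brightest probe set and a median of -0.14 over its 3 probe sets. Rbm6, another RNA-binding protein gene, had 2.60, a median of -0.65 and a lowest probe set at -1.42. Ttc14 and Cdc37l1 had 2.82 and 2.52, with lowest probe sets at -0.47 and -0.72. Gdap10, 9530059O14Rik and E030024N20Rik were above the floor in the knockout-labelled pool alone, at least 11.1-fold, 7.97-fold and 6.98-fold higher.

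Across all genes, 425 of 12244 were at least 2-fold higher in the knockout-labelled pool and 826 were at least 2-fold lower, together 10.2%, by brightest probe sets. Over all 20967 measured probe sets with 1 gene the counts were almost equal, at 1458 higher and 1470 lower. At 4-fold the counts of genes were 35 and 87. The SD of the log2 ratios over genes was 0.64, and the SD of the probe set error was 0.58, or 1.49-fold, from the 2 brightest probe sets of 5375 genes. The ratios of those pairs correlated across genes with a Pearson r of 0.41 and a Spearman rho of 0.44; genes are not independent replicates. Of 544 such genes with a brightest probe set 2-fold apart, 441 (81.1%) had a second probe set of the same sign and 183 had one that was also 2-fold apart. A 2-fold ratio of a single probe set was therefore under 2 SD of the probe set error, and that error leaves out the spread between mice.

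Genes with several probe sets in 1 direction included Rps7, Hsp90b1 and Hspa5 among the lowest, and Malat1 and Rian among the highest, in the knockout-labelled pool. All measured probe sets were at least 1.5-fold lower for 357 genes and at least 1.5-fold higher for 206. By median log2 ratio the 10 lowest were Gh, Pttg1 (-3.09), Pomc (-3.03), Rps7 (-2.89), Odr4 (-2.65), Cdc5l (-2.53), Hsp90b1 (-2.36), Nsa2 (-2.25), Hspa5 (-2.23) and Ik (-2.19). Rps7 encodes a protein of the small ribosomal subunit, Cdc5l and Ik take part in splicing, and Hsp90b1 and Hspa5 encode the main chaperones of the endoplasmic reticulum. The 10 highest were Malat1 (3.54), Crim1 (2.83), Nbeal1 (2.73), Scai (2.65), Zdhhc21 (2.46), Rian (2.27), Btg2 (2.26), Cpeb3 (2.26), 4632427E13Rik (2.23) and Sp1 (2.09). Malat1 and Rian are noncoding RNAs held in the nucleus, Btg2 is an activity-induced antiproliferative gene, and Cpeb3 regulates translation at synapses. The brightest probe sets of Malat1, Nbeal1, Scai and Sp1 had ratios of only 0.87, 0.59, 0.65 and 0.68.

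Of the 39 gene lists fixed before the data were examined, 38 had enough measured members. Of these, 4 stood above and 6 below the central 95% of random lists matched on signal. Lists of unrelated genes would be expected to give 1.9. Members of these lists may vary together and some genes are in several lists, so no excess over chance is claimed. Of all 12244 genes, 18.25% were at least 1.5-fold lower in the knockout-labelled pool and 12.46% at least 1.5-fold higher. Counts of list members are to be read against these shares. The chaperone and microglia lists were the lowest. In the list of heat shock and unfolded protein response genes, which encode chaperones but also regulators of these responses, 12 of 25 measured members were at least 1.5-fold lower in the knockout-labelled pool and 0 were higher. The list median was -0.58, at percentile 0.0 of 10000 random lists. Hsp90b1 was 5.24-fold lower, Hspa5 4.69-fold and Calr, a calcium-binding lectin chaperone of the endoplasmic reticulum, 2.74-fold (14501 and 5338 units). The highest members were Dnajb1 at 0.47 (its other probe set at -0.59), Hyou1 at 0.46 and the inducible Hspa1a at 0.35. The pituitary hormone gene Gh was also higher in the wild-type pool, by 117-fold.

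Of 21 measured microglia markers, 12 were at least 1.5-fold lower and 2 at least 1.5-fold higher in the knockout-labelled pool. Their median was -0.82, at percentile 0.0. Fcrls, an Fc receptor-like gene of microglia, was 4.10-fold lower, the complement gene C1qa 3.5-fold and the purinergic receptor gene P2ry12 2.46-fold. Cx3cr1, the fractalkine receptor gene, went the other way at 3.91-fold higher, from 87.2 to 343.6 units. Laptm5 and Cd53 had ratios of 0.69 and 0.32. Only 3 microglia markers had a second measured probe set, so almost all of these values rest on single probe sets.

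**Figure D1:**
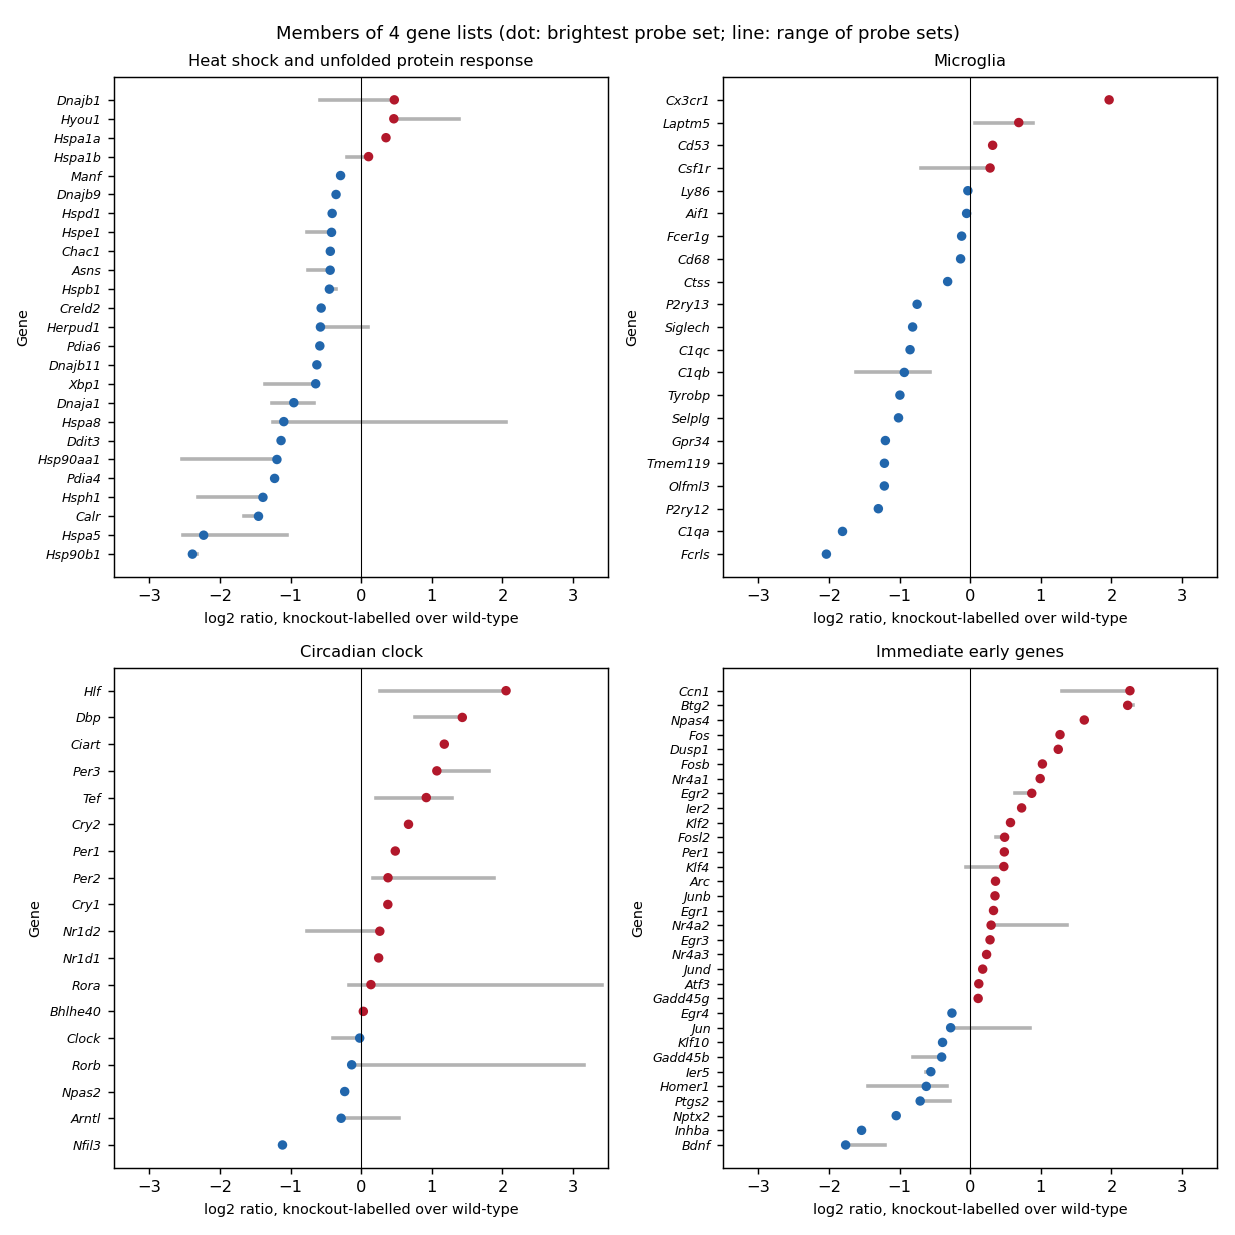
Log2 ratio of knockout-labelled over wild-type signal (x axis) for each measured gene (y axis) of 4 gene lists. Dots show the brightest probe set of a gene, red above 0 and blue below, and grey lines the range over its measured probe sets. Hsp90b1 and Hspa5 are the lowest chaperone genes, and Cx3cr1 lies apart from the other microglia markers at 1.97.

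The medians of 3 housekeeping lists, of protein turnover, translation and respiration, stood below those of random lists, while most of their genes lay within 1.5-fold. Among ubiquitin and proteasome genes, 14 of 35 were at least 1.5-fold lower and 1 was higher, with a median of -0.36 (percentile 0.28). Psma4, a core proteasome subunit, was 4.12-fold lower, and Psmd6 was highest at 0.66, although it had -0.36 when suffixed probe sets were left out. Among cytosolic ribosomal proteins, 10 of 32 were lower and 1 higher, with a median of -0.38 (percentile 0.08). Rps7 was 6.64-fold lower and Rpl4 4.49-fold, while Rpl12 was highest at 0.70. Among subunits of the mitochondrial respiratory chain, 11 of 48 were lower and 2 higher, with a median of -0.25 (percentile 2.13). Uqcrq of complex III was 4.10-fold lower, although its other probe set gave -0.13, and Ndufa2 of complex I was highest at 1.05. The respiratory list was within the central 95% of random lists when these were not matched on signal. By second brightest probe sets, chosen after the data were seen, the proteasome and respiratory lists were within it (percentiles 7.16 and 8.89). The ribosomal list was within it when suffixed probe sets, which can bind several transcripts, were left out. Random lists matched on gene length were not made for these 3 lists. Over all genes, median ratios rose with gene length, from -0.15 in the shortest of 4 equal groups to 0.03 in the longest. How far that trend enters these 3 medians was not tested.

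The medians of the circadian clock and immediate early lists stood above those of random lists, while most of their genes lay within 1.5-fold. Among circadian clock genes, 6 of 18 were at least 1.5-fold higher and 1 was lower, with a median of 0.32 (percentile 99.42). The transcription factor genes Hlf and Dbp, outputs of the clock, were 4.14-fold and 2.70-fold higher, with other probe sets at 0.27 and 0.76, and Ciart, a clock repressor, 2.26-fold. Nfil3, which opposes Dbp, had a ratio of -1.11, and Arntl and Npas2 had -0.28 (its other probe set 0.54) and -0.23. By second brightest probe sets, an alternative chosen after the data were seen, the clock list was inside the random range (percentile 95.5). Among immediate early genes, 9 of 32 were higher and 5 lower, with a median of 0.31 (percentile 99.95). Ccn1 was 4.79-fold higher, Btg2 4.69-fold and the neuronal transcription factor gene Npas4 3.06-fold. The lowest members were secreted factors: Bdnf, a neurotrophin, was 3.40-fold lower, Inhba, an activin subunit, 2.90-fold, and Nptx2, a synaptic pentraxin, 2.07-fold. By second brightest probe sets the median of the immediate early list was -0.07.

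Calcium, PKA and CREB signalling genes had a median of 0.16 (percentile 98.9), with 5 of 35 at least 1.5-fold higher and 2 lower. Pde4a, a cyclic AMP phosphodiesterase gene, was highest at 0.98, and the coactivator gene Crebbp lowest at -0.84, although another of its 3 probe sets gave 1.93. This list was inside the random range without suffixed probe sets (median -0.06), with random lists not matched on signal (percentile 97.2) and by second brightest probe sets (0.03). Genes of serine, glycine and sarcosine handling had a median of 0.24 (percentile 97.6), although 5 of 18 were at least 1.5-fold lower and only 2 higher. Sardh, which oxidises sarcosine, was highest at 0.98, with its other probe set at -0.16, and Srr, which makes D-serine, lowest at -1.11, with its 6 probe sets between -1.22 and 0.03. This list stood apart under only 2 of the 10 other settings tried, loess and no centring. The latter shifts all ratios alike and so could not change the percentile. The median of the list was -0.11 without a floor.

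The pathway of the targeted enzyme did not stand apart by brightest probe sets. In the methionine and SAM cycle, 2 of 19 measured genes were at least 1.5-fold higher and 2 lower, with a median of -0.10 (percentile 40.7) that turned to 0.05 with quantile normalization. By second brightest probe sets, chosen after the data were seen, 9 of its genes had a median of -0.55, which stood below the random range (percentile 1.85). Apip, an enzyme gene of methionine salvage, was 4.10-fold lower, and Cbs, which commits homocysteine to cysteine synthesis, 2.26-fold lower. Sardh and Pemt, which methylates phosphatidylethanolamine, were highest at 0.98 and 0.67, with signals under 200 units. Folate one-carbon genes had 3 of 19 higher and 3 lower and a median of 0.03, with the mitochondrial synthetase gene Mthfd1l highest at 1.07 and Dld lowest at -0.71. In DNA methylation and demethylation, 4 of 17 were higher and 4 lower, and the median of -0.39 lay at percentile 2.58, just inside the central range. Dnmt3a, a de novo DNA methyltransferase gene, was 2.40-fold higher with its 3 probe sets between 0.90 and 1.76, and Tet3, a demethylation enzyme gene, was lowest at -0.87. Histone and protein methyltransferases had 5 of 43 higher and 5 lower and a median of -0.07, with Kmt2b highest at 0.99 and Smyd1 lowest at -0.89, which had 0.24 when suffixed probe sets were left out.

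**Figure D2:**
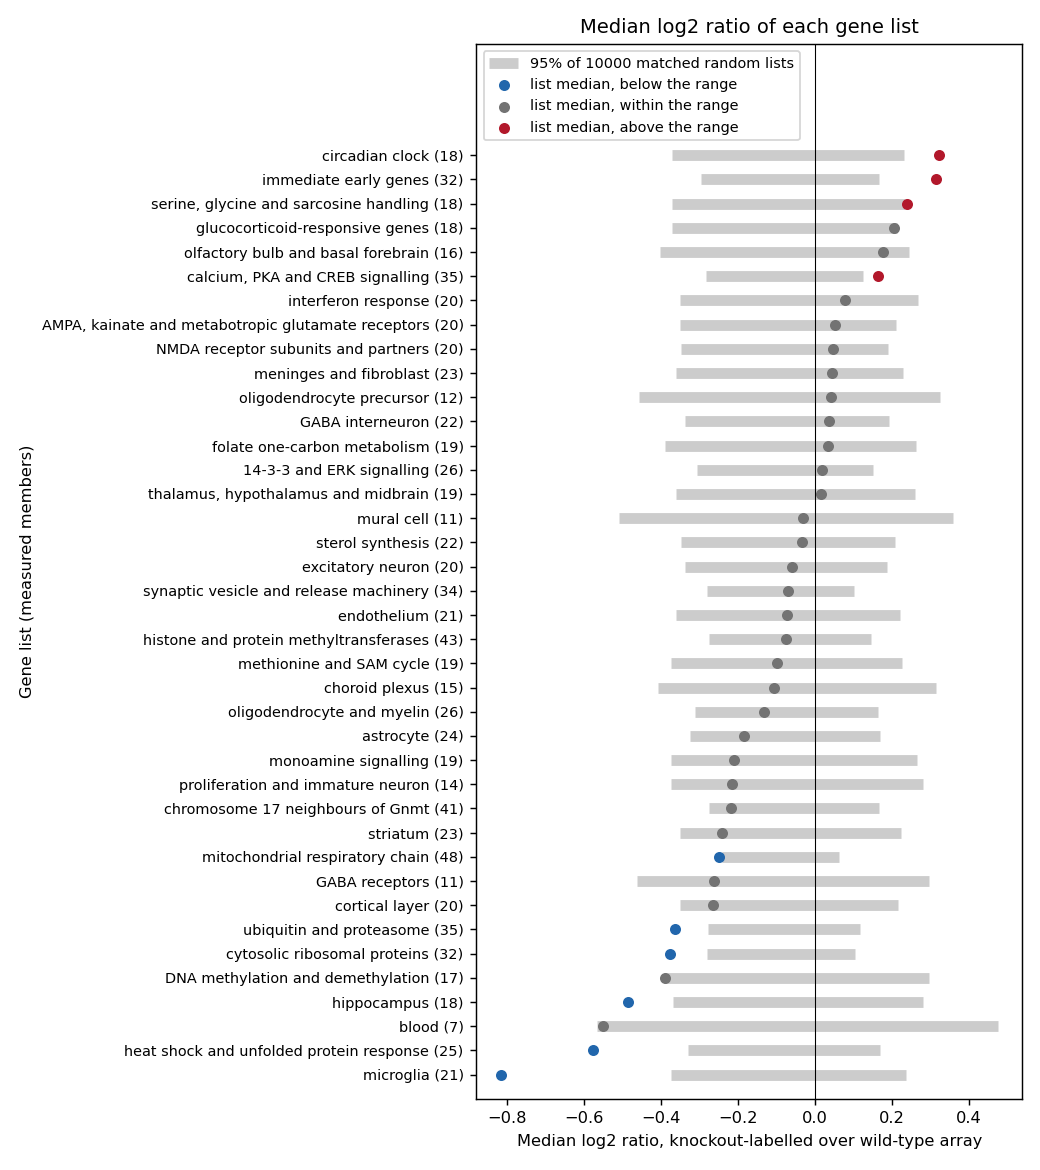
Median log2 ratio of knockout-labelled over wild-type signal (x axis) for 38 gene lists (y axis, measured members in brackets). The chromosome 17 neighbours of Gnmt are shown as a further row. Grey bars span the central 95% of medians of 10000 random lists matched on signal. The 6 lists led by microglia at -0.82 lie below their bar and the 4 led by circadian clock genes at 0.32 above it.

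Receptor and synapse lists lay inside the range of random lists, with single members apart. NMDA receptor subunits and partners had a median of 0.05, with 2 of 20 at least 1.5-fold higher and 2 lower. The scaffold gene Dlg4 was highest at 1.08 and Homer3 lowest at -1.01. AMPA, kainate and metabotropic receptor genes also had a median of 0.05, with 2 of 20 higher and 2 lower, and the AMPA receptor auxiliary gene Cacng2 was 2.86-fold lower. GABA receptor genes had a median of -0.26, with 1 of 11 higher and 2 lower. Gabrg3 was 3.77-fold higher, while Gabra5 and Gabra2 had ratios of -0.86 and -0.84, the latter with a probe set at 0.31. Monoamine signalling genes had a median of -0.21, with Maob lowest at -0.79. Synaptic vesicle genes had a median of -0.07, which was 0.19 with quantile normalization and 0.06 with loess, and 29 of 34 lay within 1.5-fold. Their extremes were the vesicle protein gene Sv2a, 3.12-fold higher, and Rab3a, 2.52-fold lower with its other probe set at -0.27. The 14-3-3 and ERK signalling list had a median of 0.02, with Dusp4 highest at 0.79 and Rap1a lowest at -0.83, with its other probe set at 0.20.

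Among cell type markers, only those of microglia stood apart, and among markers of neighbouring regions only those of the hippocampus. Astrocyte markers had 10 of 24 genes at least 1.5-fold lower and 0 higher, with Pla2g7, S100b and Gfap at -1.39, -1.23 and -1.23, but their median of -0.19 was inside the range. Oligodendrocyte and myelin markers had 7 of 26 lower and 0 higher and a median of -0.13, with Aspa lowest at -1.82. Medians were -0.06 for excitatory neurons (0.11 with quantile normalization and 0.03 with loess), -0.27 for cortical layers, 0.04 for GABA interneurons, 0.04 for oligodendrocyte precursors, -0.07 for endothelium and -0.03 for mural cells. The excitatory markers Neurod6 and Tbr1 were 3.04-fold lower and 2.08-fold higher. Hippocampal markers had 8 of 18 lower and 1 higher and a median of -0.49 (percentile 0.48), with Lefty1 at -1.38, Grp at -1.15 and the dentate gyrus marker Prox1 at 1.39. The hippocampal list was inside the range when suffixed probe sets were left out, and by second brightest probe sets of 4 genes. Medians for other tissue were 0.04 for meninges and fibroblasts, -0.11 for choroid plexus, -0.24 for striatum, 0.02 for thalamus, hypothalamus and midbrain, 0.18 for olfactory bulb and basal forebrain and -0.55 for blood, which rested on 7 genes. Proliferating cells and immature neurons had a median of -0.21, which was 0.07 with quantile normalization. The remaining lists had medians of -0.03 for sterol synthesis (0.06 with quantile normalization), 0.08 for interferon response (-0.07 with quantile normalization) and 0.20 for glucocorticoid-responsive genes (percentile 97.2), a list that stood above the random range under 5 of the 10 other settings, with medians up to 0.38. In that list, Zbtb16 and Ddit4, both induced by glucocorticoids, were highest at 2.19 and 1.49, although the other probe set of Zbtb16 gave -0.09.

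In a mixed 129/B6 background, genes linked to a targeted locus can carry alleles of another strain, so the 40 genes on each side of Gnmt on mouse chromosome 17 were examined. Of 41 measured, 15 (36.6%) were at least 1.5-fold apart, against 30.7% of all genes, and their median of -0.22 lay at percentile 6.82. Mea1 was 3.49-fold lower by its brightest probe set, with its 2 probe sets at -1.80 and -1.60. Bicral, Ubr2 and Taf8 were highest at 1.28, 1.17 and 1.15, and the other probe sets of Bicral and Ubr2 reached down to -0.62 and -0.23. Among the genes named above for extreme or consistent ratios, Cdc5l, Zfp942 and Crim1 are also on chromosome 17. By brightest probe sets, Cdc5l was 3.88-fold and Zfp942 6.65-fold lower in the knockout-labelled pool, and Crim1 was 15-fold higher. Their distance from Gnmt is not given here, and their linkage to it was not tested.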

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

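The tests of genotype, of hypothalamic tissue as the whole source, of female mice in the pool, of nuclear noncoding RNA, of second probe sets and of the spread of microglia markers were chosen after the results they concern had been seen. The others were set before their result was seen, those of pituitary tissue and of any share of hypothalamic tissue on marker lists written after Gh and Pomc had been noticed.

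The beta-actin control probe sets, which enter no gene value, were 2.72-fold (3' end), 2.69-fold (5' end) and 3.88-fold (middle) higher on the knockout-labelled array. Under the other scalings they were between 2.71-fold and 4.24-fold higher, and the brightest ordinary probe set of Actb was 3.77-fold higher, although without suffixed probe sets Actb had a log2 ratio of -0.32. Only actin controls higher on that array were flagged. The bright control probe set MURINE_b1 went the other way, 3.71-fold lower (40239 units on the wild-type array and 10928 on the other). The control MURINE_B2 was 1.04-fold higher. Of 2961 measured probe sets that name no gene or several genes and so were left out of gene values, 707 (23.9%) were at least 2-fold higher on the knockout-labelled array and 148 (5.00%) at least 2-fold lower, against 6.95% and 7.01% of probe sets with 1 gene.

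Pituitary hormone transcripts were at least 2-fold higher in the wild-type pool for 5 of 6 hormone genes above the floor, led by Gh at 23223 against 200 units and followed by Pomc at 3127 against 394.3 units, with Prl and Cga below the floor in the other pool. Pituitary tissue carried into the wild-type pool may be the source: of 10 pituitary genes other than hormones above the floor on either array, 4 (Trhr, Dlk1, Chgb and Scg2) were at least 1.5-fold higher there and 1 in the other pool. Brain tissue also expresses those 4 genes, and the pituitary transcription factor genes Pitx1, Lhx3 and Tbx19 were below the floor in both pools. Ghrhr and Gnrhr were above the floor in the wild-type pool alone, with lower bounds of 1.23-fold and 1.48-fold. Sox3 and Nr5a1 were above it in the other pool alone, with bounds of 1.57-fold and 1.19-fold. All of these signals lay near the floor. Hypothalamic tissue as the whole source is argued against, since 7 of its peptide genes had a median log2 ratio of 0.016. Its range of -0.271 to 0.304 was taken from the 95% error of a mean over these genes and covers no spread between pools. Signals below the floor had been set to it. A median below -1 had been set beforehand for any share of hypothalamic tissue, a test that stayed undecided. That bound was applied to the whole source afterwards. A small share stays open because some of these genes lay near the floor and some are expressed in cortex. An effect of genotype cannot be told apart from a difference in dissection, because there was 1 pool per genotype.

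Xist was at least 39.6-fold higher in the knockout-labelled pool although both pools are labelled male, and a pool made up of females alone is argued against by the 3 Y-linked genes above the floor there, each with a log2 ratio above -1. A single female of 3 would give Y-linked genes a ratio of -0.585, and their median of -0.222 lay 0.363 above that. The bound written for this test, 0.333, is the probe set error of a mean over these genes and not of a median. Its 95% range of 0.653, the bound applied, was wider than the gap, so the median did not decide this. Single probe sets did not settle it. Uty (at least 3.62-fold and 1.35-fold higher) and Kdm5d (at least 1.58-fold) had probe sets above the floor in that pool alone. However, the dimmest measured probe set of a gene was more often 2-fold higher than lower in the knockout-labelled pool (620 against 403). Kdm5d by its brightest probe set had -0.85 and another probe set of Uty -0.56. With 3 genes and an error that leaves out the spread between mice, a female is not excluded. More nuclear noncoding RNA on that array is argued against as the whole cause, since 11 other such RNAs had a median of 0.872 (SD 0.761) against the bound of 5.306 for Xist; a second form of this test, on the highest probe set (Malat1, 4.231), was tried after that result, left it open and was dropped because it rested on a selected maximum. With a single pool, a sex difference in its mice would be mixed with genotype in every other ratio.

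The chaperone list (heat shock and unfolded protein response) and the microglia list were the lowest in the knockout-labelled pool. A trend with probe set identifier number and signal is argued against as the whole cause. Matched on blocks of 5000 identifier numbers and on signal, random lists put the chaperone median at percentile 0.09 and the microglia median at 0.0. A trend with gene length (percentile 0.12) and errors of single probe sets (median -0.891 over second probe sets of 15 genes of the list, against a random range of -0.414 to 0.301) are argued against in the same way for the chaperone list. A lower share of microglia could lower its markers together, but their SD of 0.913, close to the upper limit of 0.947 for random lists, did not decide this. Genotype, the pituitary transcripts of the wild-type pool, the sex of the mice and the handling of 1 pool stay open for both lists and were not tested.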

How the results depend on the processing

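No paired analysis was possible because each group had 1 array and no test was made. The second brightest probe set was an alternative chosen after the data were seen, and so was the width of spread within which a value counts as kept: for lists and genes 1 SD was first tried, under which 62 of 377 list values moved, and it was widened to a 95% range, under which 16 moved and 3 reversed. The microglia, chaperone, proteasome, immediate early and circadian lists stood apart in the same direction under all 9 settings set beforehand, with medians from -0.96 to -0.80, -0.67 to -0.46, -0.47 to -0.18, 0.18 to 0.46 and 0.16 to 0.43. By second brightest probe sets, with too few microglia genes, only the chaperone and ribosomal lists of the 10 that stood apart still did; the proteasome (-0.32), circadian (0.41), immediate early, respiratory (-0.26), hippocampal, calcium and serine (0.14) lists were inside the random range, while the methionine cycle stood below it and the thalamus and olfactory lists above. Under the 9 settings, the ribosomal, hippocampal and respiratory lists stood apart under 8, the calcium list under 7 and the serine list under 2. Of these settings, no centring shifts all ratios alike, so it could not change any percentile. Changing the floor kept each gene's probe set, so members counted again kept their ratios apart from a common shift. The other floors changed only which genes were counted, and they are no independent repeats of the main setting. The glucocorticoid list, inside the random range in the main setting, stood apart under 5, blood under 3, DNA methylation under 2, and olfactory bulb and immature neurons under 1 each. Of 842 values of named genes under other settings, 19 moved, 7 reversed and 816 did neither. The spread allowed for a gene was 1.132 log2 units. Under the other floors and under no centring, a gene's ratio could change only by the centring constant. The 816 values are therefore no measure of how stable single genes are.

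With the floor at the 25th percentile the SD of ratios over genes was 0.67 and the correlation of probe set pairs 0.346; at the 60th they were 0.60 and 0.482, with 479 genes 2-fold lower. Without a floor, 1807 genes were 2-fold higher and 2654 lower, the SD was 1.14, the correlation 0.158, and the 1 Gnmt probe set counted as measured; dim signals enter there by construction. The serine list then reversed to -0.11. The SD was 0.65 with quantile normalization, where synaptic vesicle genes had 0.19 and the respiratory list -0.053, and 0.62 with the median of all probe sets, where Rbfox2 had -0.14 and Rbm6 -0.65. Without suffixed probe sets the SD was 0.66, the correlation 0.271, folate genes -0.30, immature neurons 0.34, calcium signalling -0.059, Rbfox2 -0.19, Ttc14 -0.091, Psmd6 -0.36, Actb -0.32 and Smyd1 0.24. By second brightest probe sets medians were -0.066 for immediate early genes, -0.89 for chaperones, -0.55 for the methionine cycle, 0.33 for methyltransferases, -0.26 for AMPA, kainate and metabotropic receptors, 0.27 for GABA receptors, -0.28 for interferon response, 0.30 for cortical layers, 0.26 for astrocytes, 0.61 for mural cells, 0.86 for thalamus, hypothalamus and midbrain, 0.75 for olfactory bulb and 0.14 for immature neurons. Beyond the change in probe sets or genes counted, the cause of these shifts was not tested. How far low signal over background limits dim genes was not separated from the change in genes counted; the pair correlation was lower at lower floors.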

Other observations

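Several noncoding RNAs held in the nucleus were higher in the knockout-labelled pool, by a list written after some of these values had been seen. By brightest probe sets 5 of 11 such RNAs without Xist were at least 2-fold higher there and 0 at least 2-fold lower. Of their 33 measured probe sets, 11 of which are of a single RNA and 4 of Malat1, 17 were at least 2-fold higher and 0 lower; 1 RNA had both probe sets below 0, and Malat1 probe sets ranged from 0.87 to 4.23. Among genes of the reference class lncRNA, 25 of 321 were at least 2-fold higher (7.79%) and 10 lower (3.12%), with a median of 0.14. Protein-coding genes had 389 of 11821 higher (3.29%) and 813 lower (6.88%), with a median of -0.07. Median ratios over 4 equal groups of genes by length, shortest first, were -0.15, -0.07, -0.02 and 0.03, and the Spearman rho of length and ratio across genes was 0.115.

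The dimmer probe sets of a gene differed more between the pools than its brightest. Among 5375 genes with 2 or more measured probe sets, the brightest was at least 2-fold higher in the knockout-labelled pool for 237 and lower for 307, while the dimmest was higher for 620 and lower for 403. At 4-fold, 157 dimmest probe sets were higher and 41 lower.

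Spiked control transcripts did not all match between the arrays. The mean signal of bioC was 3220 units on the wild-type array and 1054 on the other, 3.08-fold lower, while bioB was 1.38-fold and cre 1.23-fold lower and bioD had a wild-type over knockout-labelled ratio of 0.954. The ratio of 3' to 5' control signals was 3.71 and 3.76 for Actb and 0.932 and 1.02 for Gapdh, in the wild-type and knockout-labelled pools.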
